A study of Mus musculus with 50 samples.

How the data were processed

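The series holds 50 libraries in 16 groups: 25 from the immunoprecipitate (IP) and 25 from the whole lysate (Input) of mouse lumbar spinal cord. Per the submitters' labels, the mice carry a RiboTag allele, which puts an HA tag on ribosomal protein RPL22 in cells with ChAT-Cre, so that RNA on tagged ribosomes of cholinergic neurons can be pulled down with an antibody to HA. The cDNA kit named in the labels does not mark the strand, so reads of overlapping genes on opposite strands were not told apart. The labels give a strain background of C57BL/6 and no sex, and do not state the kind of injury or the ALS allele.

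The authors deposited expected counts of fragments and FPKM values, which they had computed with Cuffdiff, as tables with 1 value per gene and library. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.2a, handled with SAMtools 0.1.19 and quantified with Cufflinks 2.2.1 and Cuffdiff. The authors also deposited log2 fold changes and q-values for each comparison, which are given here only as the authors' values and were not used in any test. Of the raw fragment values, 5.4% were not whole numbers, and all were rounded before testing. The tables hold 46073 genes, of which 45226 have an identifier in GENCODE M21, used for biotypes, and 23726 have the same chromosome, start and end there. Coordinates are those of the deposited tables on mm10 with 1 added to the start, and a locus in these tables can span neighbouring genes. Between 19 and 29 genes per table with a FAIL status were left out. In 1 of the authors' Input comparisons, 27 gene symbols had been turned into dates, so genes were matched by identifier. Every column of per-library values was used (0 left over).

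Libraries were grouped by the names in the tables. At 3 months the tables name 4 libraries Mut and 3 WT in each fraction, while the labels list 3 RiboALS and 4 RiboWT samples. The tables' names were used, and 3-month groups are called Mut and WT in the report for that reason. Sod1 stood at 23179 to 26329 FPKM in the 4 Mut IP libraries and 253 to 283 in the 3 WT. All other groups have 3 libraries. The labels give each library a mouse ID, so RiboALS and RiboWT libraries of a fraction come from separate mice and the p-values measure spread between them. The labels give the same 3 mouse IDs to the D7 and UNJ libraries, and the same mouse gave an IP and an Input library. The table columns carry replicate numbers and no mouse ID, so no mouse could be used as a block. The tests therefore treat the libraries as separate.

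The comparisons, tests, gene lists and alternatives were written down before the data were examined. Each of the 8 main comparisons (D7 against UNJ, and RiboALS against RiboWT at 1, 3 and 4 months, in each fraction) was fitted on its own table with edgeR 4.0.16: TMM scaling, filterByExpr, quasi-likelihood F tests and Benjamini-Hochberg adjustment over all tested genes. A gene passed at an adjusted p under 0.05. Log2 fold changes are edgeR estimates with their standard error (SE), and levels are FPKM as mean ± SD. A further 8 interaction tests, on joined tables, asked whether an effect differed between IP and Input, between ages, or between injury and 4-month RiboALS. Genes with 0 fragments in every control library are given as a lower bound of the fold, with a floor of 3 fragments over the control group.

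Gene lists (32, each with at least 3 measured members) were written from general knowledge of cell types and pathways. They were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, on log2 CPM with a prior count of 2, with adjustment over the 32 lists. The same test with a correlation estimated from the libraries, and fry, were alternatives. Counts of list members that rose or fell use the adjustment over all genes. Counts marked "over the list alone" adjust over the list's members only. The overlap of calls between comparisons was tested with a one-sided Fisher exact test over genes tested in both.

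Other settings, fixed at the start, were DESeq2 1.42.0 (size factors within edgeR, and its Wald test), limma on log2 FPKM with 1 or 0.1 added, no filter, an FPKM filter, leaving out each library in turn, the replicate number as a block for D7, and the 3 ages in 1 fit. A threshold of 0.1 and the authors' calls were used for overlaps. After the results were seen, 4 kinds were added: a term for a 3-month library batch (inferred from the share of fragments in Rn18s-rs5, as the labels name none), the larger batch alone, a term for the level of myelin transcripts in each IP library, and a term for Y-linked transcripts at 1 and 4 months. A planned covariate from sample number ranges and a mouse block for interactions were not run, because the columns do not name the mouse.

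Genes are named by a fixed rule: an adjusted p under 0.05, a mean of at least 1 FPKM in the higher group, and a symbol that is not a bare model identifier (Gm with digits, or ending in Rik). The 10 largest changes in each direction in the IP (5 in the Input and in interactions) and up to 4 members of each passing list by smallest adjusted p could be named. Chat, Slc18a3, Isl1, Rpl22, Sod1, Atf3, Gfap and Aif1 were always given. Where fewer than 5 genes passed, the 5 with the smallest p came under the rule, though not all of them are printed. Over all comparisons 322 genes came under this rule. Genes named outside it include Gm8566, a copy of Sod1, Xist and Tsix, a Dst entry, Srd5a2, and members of lists that did not pass.

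As a self-test, 200 genes with planted 2-fold or 4-fold changes were added to data simulated from each comparison. For 4-fold changes edgeR recovered 92%, 77%, 74% and 97% in the IP (D7, 1, 3 and 4 months) and 100%, 94%, 92% and 94% in the Input. For 2-fold changes it recovered 68%, 52%, 36% and 84% in the IP and 83%, 82%, 64% and 79% in the Input. In the interaction tests it recovered 21% to 65% of 2-fold and 63% to 93% of 4-fold changes. Between 5 and 23 genes without a planted change were called. A planted list was found by camera in every comparison. At the preset correlation camera also called 1 or 2 lists without a planted change in 7 of 8 comparisons, and with an estimated correlation 0. Genes were drawn independently there, so these counts cannot give the rate of false list calls among correlated genes. Regrouped real libraries gave up to 23 lists at the preset correlation. Scripts ran under R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.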

Results

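The data came from lumbar spinal cord of mice in which ribosomal protein RPL22 carries an HA tag in cholinergic neurons (RiboTag with ChAT-Cre). An antibody to HA pulls down RNA on tagged ribosomes, the immunoprecipitate (IP), which is read as the translating RNA of motor and other cholinergic neurons. The Input is RNA of the whole lysate, from all cells of the cord. There were 50 libraries in 16 groups. They cover cord after an injury whose kind the labels do not state (D7, 7 days) against uninjured cord (UNJ), and RiboALS against RiboWT mice at 1, 3 and 4 months. Groups had 3 libraries per fraction, except that at 3 months the tables name 4 libraries Mut and 3 WT. Libraries held 17.5 to 44.8 M fragments in the IP and 19 to 42.4 M in the Input, and 19850 to 24553 genes were detected per library. Values are mean ± SD FPKM with n libraries, log2 fold changes are edgeR estimates ± SE, p-values are edgeR or camera p-values adjusted over genes or lists, and coordinates are on mm10.

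The first question was whether the IP held motor neuron RNA. Chat, the enzyme that makes acetylcholine, stood at 31.4 ± 3.65 FPKM in the UNJ IP and 9.18 ± 0.463 in the Input (n = 3 each), a ratio of 3.42. Chat and Slc18a3, the vesicular acetylcholine transporter, share the locus chr 14:32408203–32483539, so the split of reads between them is uncertain. Over the 14 motor neuron and cholinergic genes, the median log2 of IP over Input lay between 2.36 and 3.06 in every group, and motor neuron subtype genes lay between 1.16 and 1.68. Genes of several other cell types were depleted: myelin genes at −4.93 to −2.78, astrocyte genes at −3.91 to −2.03, homeostatic microglia genes at −4.38 to −1.77 and inhibitory neuron genes at −2.85 to −2.02. Blood and immune genes were less depleted in some groups (−2.53 to −0.54), and Schwann cell genes lay near 0 (−0.61 to 0.15). For Aif1 of microglia the ratio of IP to Input ranged from 0.2105 in 4-month RiboALS to 0.7451 at D7.

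**Figure D1:**
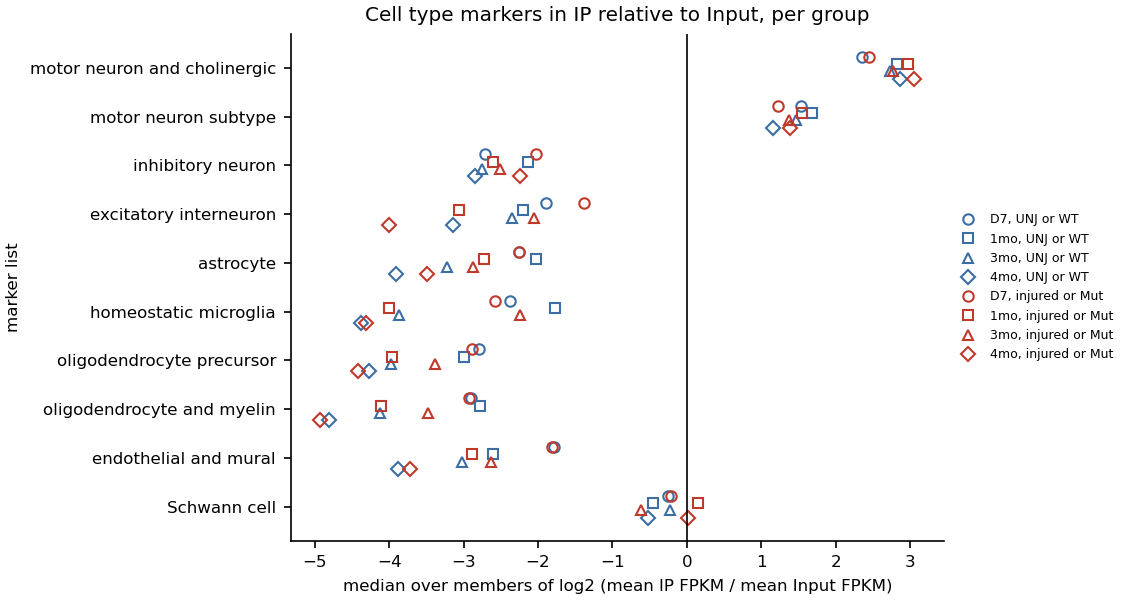
Median log2 of IP over Input FPKM for each gene list and group.

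The second question was which genes changed in the translating RNA after injury (D7 against UNJ, IP, n = 3 each). Sprr1a, a small proline-rich protein made by regrowing neurons, rose from 5.5 ± 2.58 to 1669 ± 476 FPKM (log2 8.27 ± 0.33). Atf3, a stress transcription factor that drives axon regrowth programmes (chr 1:191170296–191218039), rose from 1.69 ± 0.949 to 226 ± 91.2 FPKM (7.07 ± 0.41). Ccl7, a chemokine that attracts monocytes, rose from 0.966 ± 0.746 to 389 ± 114 FPKM (8.71 ± 0.37). Vax2, a homeobox factor of the eye, rose from 0.0235 ± 0.0204 to 14 ± 3.85 FPKM (8.87 ± 0.46), Fst, which binds activin, rose by 7.79 ± 0.38, and Gpr151, an orphan receptor of the habenula, rose by 7.80 ± 0.50. Genes with 0 fragments in all UNJ libraries rose at least 90.5-fold (Sh2d1b2, an adaptor of natural killer cells), 78.5-fold (Mup3, of a family of near copies and so uncertain), 46.4-fold (Kera, a matrix proteoglycan) and 35.5-fold (Csn3, a milk casein). With edgeR 289 genes rose and 7 fell of 16495, against 146 in all with limma and 496 with no filter (63 falling). Only 167 of these 296 passed in every fit without 1 library, and the count dropped to 189 without UNJ replicate 1.

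By fixed list, 15 of 37 regeneration-associated genes rose and 0 fell (23 rose over the list alone), with a camera adjusted p of 6.52e-34, or 0.136 with an estimated correlation. Gap43, a growth cone protein, rose from 190 ± 29.5 to 1080 ± 198 FPKM (2.54 ± 0.17, n = 3), and Ngfr, the low-affinity neurotrophin receptor, rose by 4.63 ± 0.39. Of 17 neuropeptide genes 8 rose (10 rose and 1 fell over the list alone), with an adjusted p of 1.79e-18 and 0.0278 with an estimated correlation, the only IP list to pass both. Npy, a vasoactive peptide, rose from 9.51 ± 2.21 to 528 ± 30.3 FPKM (5.81 ± 0.19), Gal, a peptide made by injured neurons (chr 19:3409919–3414472), from 21.3 ± 1.67 to 1030 ± 455 (5.61 ± 0.31), and Crh and Grp rose by 4.31 ± 0.36 and 3.28 ± 0.28. Of 16 disease-associated microglia genes 6 rose (11 over the list alone), with an adjusted p of 2.24e-14 and 0.191 with an estimated correlation. These include Lgals3, a lectin of phagocytes (2.48 ± 0.27), Cd63, a lysosomal membrane protein (2.22 ± 0.20), and Fabp5, a fatty acid carrier (0.97 ± 0.16). In the Input these 3 changed by 0.28, 0.06 and −0.08, and each passed the interaction test as more positive in the IP. For them the name of the list does not give the source cell. Of 16 matrix genes 3 rose, among them Timp1, an inhibitor of matrix proteases, from 1.36 ± 0.247 to 62.8 ± 12.7 FPKM (5.52 ± 0.24), with an adjusted p of 0.00042 and 0.357 with an estimated correlation.

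Several lists moved by small amounts with few or no members passing. Interferon genes (17, adjusted p = 6.87e-05, 0.366 with an estimated correlation, 0 rose), homeostatic microglia genes (12, 0.00118, 0.470, 0 rose), ribosomal protein genes (67, 3.82e-05, 0.472, 0 rose) and cholesterol synthesis genes (23, 0.000276, 0.421, 0 rose) were higher. The homeostatic microglia list did not pass without D7 replicate 2 (0.43), at a mean log2 level of 3.87 against 2.43 and 2.08 in the other D7 libraries, or without UNJ replicate 0 (0.214), and UNJ replicate 2 stood at 3.00 against 1.48 and 1.93. Astrocyte genes (16, 0.0194, 0.357) were higher with 2 rising, Vim, an intermediate filament (1.33 ± 0.23), and Serpina3n, a protease inhibitor with near copies (1.29 ± 0.23). Inhibitory neuron (0.0194, 0.366), excitatory interneuron (0.0217, 0.357) and blood and immune genes (0.0217, 0.445) were higher with 1 gene rising in each. Ion channel and receptor genes (36, 8.61e-05, 0.398) and synaptic vesicle genes (22, 0.0398, 0.366) were lower with 0 falling, and the motor neuron list was lower (14, 0.0099, 0.366) with 0 falling and Gfra1, a receptor for GDNF, rising by 0.92 ± 0.18. The 7 genes that fell were Crybb2, a crystallin (−2.65 ± 0.49), Htr3a, a serotonin-gated channel (−1.23 ± 0.26), Nog, which blocks BMP (−1.23 ± 0.25), Tcea3 (−0.74 ± 0.16), C1ql2 (−0.70 ± 0.14), Ptn (−0.67 ± 0.15) and Zfp365 (−0.61 ± 0.13). Chat (31.4 ± 3.65 against 22.5 ± 5.22 FPKM, adjusted p = 0.328), Slc18a3 (0.769), Isl1 (0.484), Rpl22 (0.929), Sod1 (0.53), Gfap (0.397) and Aif1 (0.138) did not pass.

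The whole lysate of the same cords was asked the same question (D7 against UNJ, Input, n = 3 each). Sprr1a rose from 0.408 ± 0.418 to 98 ± 38.5 FPKM (7.99 ± 0.43) and Atf3 from 0.922 ± 0.21 to 32 ± 13.3 (4.73 ± 0.34). The chemokine genes Ccl7 and Ccl2 rose by 5.50 ± 0.37 and 4.34 ± 0.40. Of 12 homeostatic microglia genes 11 rose, with a camera adjusted p of 8.08e-42 and 0.0414 with an estimated correlation. Csf1r, the receptor microglia need to survive, rose from 27 ± 0.685 to 55.4 ± 3.58 FPKM (0.99 ± 0.06), and Tmem119, a microglial membrane protein, from 20.1 ± 0.907 to 34.8 ± 1.49 (0.78 ± 0.07). Of 12 complement genes 5 rose (2.29e-12, 0.0453 with an estimated correlation), among them C1qc, from 60.5 ± 4.75 to 131 ± 7.67 FPKM, and C1qa, from 55.1 ± 7.32 to 112 ± 5.2. Interferon genes (20) rose in 4 cases and in 11 over the list alone (1.6e-17, 0.258 with an estimated correlation), led by Usp18, which removes ISG15 (1.54 ± 0.26). With edgeR 187 genes passed of 16698, 10 of them falling and the rest rising. Limma gave 39, no filter 362 and the replicate number as a block 327 (42 falling). Of the 187, 77 passed in every fit without 1 library. Without D7 replicate 2 the count dropped to 86, and without UNJ replicate 1 to 94.

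Of other Input lists, 7 of 38 regeneration genes rose (1.06e-10, 0.287 with an estimated correlation), 4 of 19 disease-associated microglia genes (4.7e-10, 0.217), including Trem2, a microglial lipid receptor (0.90 ± 0.10), and 1 of 11 antigen presentation genes (1.38e-09, 0.310; 5 over the list alone). Neuropeptide genes rose in 5 cases and fell in 1 of 17 (1.9e-07, 0.310), with Gal up by 1.39 ± 0.18 and Calcb, a CGRP gene of motor neurons, down (−0.66 ± 0.14). Of 30 lysosome and autophagy genes 6 rose (5.97e-06, 0.310), led by Ctss, a protease of microglia (1.25 ± 0.08), though the list median was −0.00 and its mean 0.14. Oxidative phosphorylation genes (46, 3.49e-09, 0.596), mitochondrial genome transcripts (13, 3.24e-05, 0.461) and ribosomal protein genes (66, 0.00422, 0.753) were lower with 0 falling, the last turning higher without UNJ replicate 0 (0.485). The motor neuron list was lower (14, 0.000619, 0.374), with Slc5a7, the choline transporter, falling (−0.42 ± 0.09) and Gfra1 rising (0.49 ± 0.11). Gfap, the astrocyte filament, rose (0.29 ± 0.06, 689 ± 39 to 863 ± 56.8 FPKM) and so did Aif1 of microglia (0.78 ± 0.17), while Chat (9.18 ± 0.463 against 6.98 ± 0.636, adjusted p = 0.075), Slc18a3 (0.503) and Isl1 (0.856) did not pass.

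An interaction test asked which injury effects differed between IP and Input (n = 3 per group). Npy rose more in the IP (difference 5.55 ± 0.26, adjusted p = 2.65e-09), as did Crym, a thyroid hormone binder (5.14 ± 0.61), Gpr151 (5.00 ± 0.85), Cyp26a1, which breaks down retinoic acid (4.47 ± 0.95), and Gal (4.23 ± 0.41). Itgb5, an integrin subunit, was the only gene in the other direction (−0.66 ± 0.12). In all 82 genes were more positive in the IP and 1 less, and 49 of 83 held in every fit without 1 library. The count was 55 without UNJ Input replicate 1 and 160 without UNJ IP replicate 0. For Atf3 the difference of 2.35 ± 0.67 did not pass (adjusted p = 0.248).

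At 1 month the question was which genes differ in the translating RNA of young RiboALS mice (IP, n = 3 each). Sod1, the superoxide dismutase gene mutated in some familial ALS (chr 16:90220742–90226322), rose from 228 ± 42.3 to 23490 ± 1399 FPKM (6.69 ± 0.17, adjusted p = 1.46e-05). Gm8566, a processed pseudogene of Sod1 (chr 6:67205619–67206083) with 455 of 465 bases equal, rose from 3.25 ± 3.94 to 11460 ± 736 FPKM (11.93 ± 0.67), so which of the pair each read came from is uncertain. More RNA of mouse Sod1 alone would keep the split of reads between the pair. The larger rise of Gm8566 (11.93 against 6.69) argues against that. Whether the added reads come from a transgene was not determined. With edgeR these were the only 2 of 16528 genes to pass, against 730 at an unadjusted p under 0.05, 5 with DESeq2 and 4 with limma. The next smallest p-values were those of Slc16a6, a ketone transporter (0.83 ± 0.09, adjusted p = 0.148), and Odc1, which starts polyamine synthesis (0.51 ± 0.06, 0.205). Chat (66.7 ± 7.73 against 71 ± 1.68 FPKM, adjusted p = 0.878), Slc18a3 (0.85), Isl1 (0.85), Rpl22 (0.917), Atf3 (0.999), Gfap (0.85) and Aif1 (0.85) did not pass.

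Lists of other cell types were lower at 1 month, with 0 members falling in any of them and every adjusted p at 0.548 or above with an estimated correlation. They were homeostatic microglia (2.16e-05, median −2.33), myelin (5.4e-05, −1.42), oligodendrocyte precursor (0.000257), disease-associated microglia (0.000585), interferon (0.0013), inhibitory neuron (0.00142), astrocyte (0.00645), excitatory interneuron (0.0124), complement (0.0278) and blood genes (0.0285). Libraries stood apart within groups, with mean log2 levels of myelin genes of 4.55, 7.66 and 6.86 in RiboWT and 4.36, 4.38 and 6.48 in RiboALS. With a term for that level 9 lists passed instead of 19, and the astrocyte (0.181), myelin (0.669) and excitatory interneuron lists (0.564) turned higher. Ribosomal protein genes (0.00645, 0.74 with an estimated correlation) and mitochondrial genome transcripts (0.0103, 0.548) were lower as well, but the ribosomal protein list turned higher without RiboWT replicate 0 (0.762). Higher lists, also at 0.548 with an estimated correlation, were heat shock (2.56e-05), cytoskeleton (4.2e-05), motor neuron (0.000353), ALS-linked (0.00113, with Sod1 rising), regeneration (0.0124), synaptic vesicle (0.0345) and ion channel genes (0.0346), with median log2 changes of 0.15 or less. The interaction of fraction and genotype gave 0 genes with edgeR, the only tool run on interactions, 872 at an unadjusted p under 0.05, and Sod1 at 0.66 ± 0.15 (adjusted p = 0.929).

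In the 1-month Input (n = 3 each) Sod1 rose from 92.9 ± 6.3 to 6067 ± 218 FPKM (6.03 ± 0.05) and Gm8566 by 11.14 ± 0.13. The only other gene to pass, of 3, was a Dst entry, of a cytoskeletal linker gene, which had 0 in all RiboWT libraries and 0.111 ± 0.0337 FPKM in RiboALS. Its identifier is not in GENCODE M21 and it overlaps other Dst entries, so it is uncertain. Cholesterol synthesis (1.04e-06), interferon (1.67e-05), blood (0.00174), myelin (0.00198) and oligodendrocyte precursor genes (0.028) were lower, and motor neuron (2.98e-06) and neuropeptide genes (0.000239) higher, with 0 members passing and adjusted p-values of 0.509 to 0.662 with an estimated correlation. Slc18a3 (35.1 ± 2.2 against 43.3 ± 3.67 FPKM, adjusted p = 0.632) and Chat (0.941) did not pass. Without RiboWT replicate 0 there were 6 genes, with DESeq2 12, with limma 8 and with no filter 123.

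At 3 months the same question was put to libraries named Mut (n = 4) and WT (n = 3) in the tables, while the labels list 3 RiboALS and 4 RiboWT samples. Every direction given here follows the tables' names, and the Sod1 level of each library goes with those names. In the IP, Sod1 rose from 266 ± 15.4 to 24710 ± 1370 FPKM (6.52 ± 0.10) and Gm8566 by 9.98 ± 0.84. Atf3 rose from 0.634 ± 0.0476 to 29.3 ± 8.17 FPKM (5.46 ± 0.35, adjusted p = 0.000676), Fgf21, a stress-induced hormone (chr 7:45613907–45615490), from 1.37 ± 0.213 to 28.8 ± 7.72 (4.37 ± 0.28), and Mmp12, a macrophage elastase, from 0.0117 ± 0.0202 to 6.46 ± 3.4 (9.03 ± 0.85). Phgdh, the first enzyme of serine synthesis (chr 3:98313170–98339990), rose from 0.977 ± 0.264 to 12.2 ± 2.02 FPKM (3.16 ± 0.25) and Psat1, the next enzyme, from 32.7 ± 2.79 to 67.7 ± 5.97 (0.99 ± 0.11). The Y-linked genes Ddx3y (0.00508 ± 0.0088 against 18.4 ± 2.06 FPKM), Eif2s3y, Uty and Kdm5d rose, and the overlapping Xist (−7.09 ± 0.80) and Tsix (−6.01 ± 0.64) fell. Ddx3y was over 1 FPKM in 4 of 4 Mut and 0 of 3 WT libraries, so Y-linked expression and the tables' group names coincide. With edgeR 11 genes rose and 2 fell of 16489, 7 of these 13 in every fit without 1 library, against 841 at an unadjusted p under 0.05, 103 with DESeq2 and 15 with limma. The IP libraries Mut replicate 2 and WT replicate 2 held 0.591% and 0.584% of fragments in Rn18s-rs5, against 0.097% to 0.145% in the others. The labels name no batch, but with this pair treated as a batch, 112 genes passed with a batch term and 172 in the other libraries alone.

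**Figure D2:**
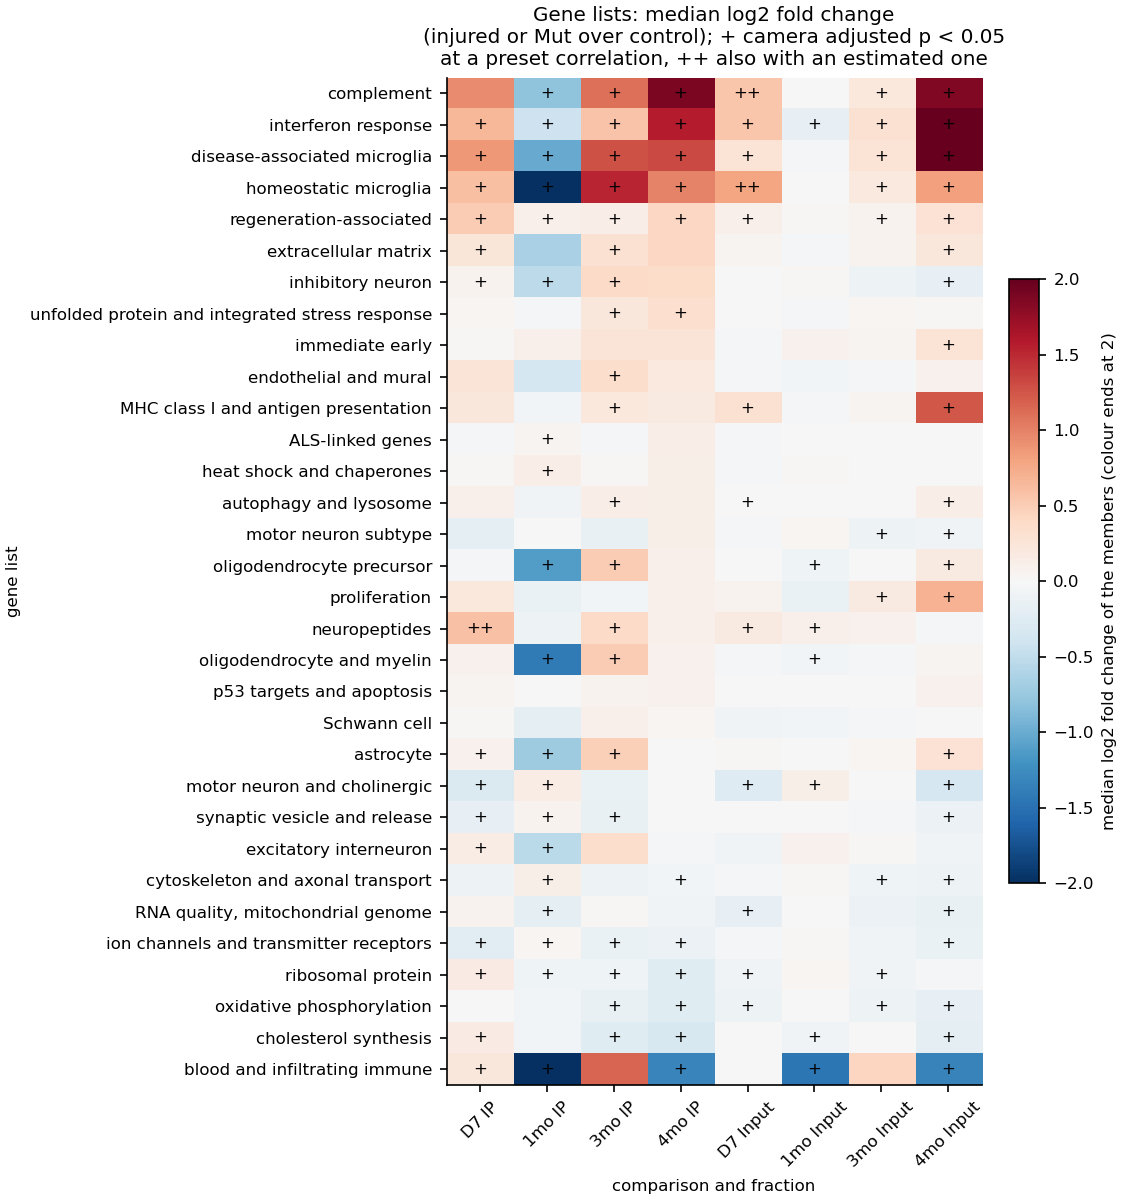
Median log2 fold change of each gene list in the 8 main comparisons, with camera calls.

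Of 29 unfolded protein and integrated stress response genes 2 rose in the 3-month IP, Phgdh and Psat1 (7 over the list alone), with an adjusted p of 2.99e-08, or 0.0776 with an estimated correlation. Of 37 regeneration genes 1 rose (5 over the list alone, 5.56e-07, 0.0698), while Sprr1a (2.2 ± 2.47 against 45.7 ± 14.4 FPKM, adjusted p = 0.23) and Ngfr (0.138) did not pass. Disease-associated microglia genes (17, 9.1e-10, 0.169) were higher with 0 rising (4 over the list alone), as were myelin (8.54e-07, 0.416), astrocyte (2.6e-06, 0.169), homeostatic microglia (2.11e-05, 0.416), interferon (0.00124, 0.416), matrix (0.00165, 0.392), lysosome (0.0024, 0.392), antigen presentation (0.00382, 0.350), neuropeptide (0.00382, 0.392), inhibitory neuron (0.00676, 0.499), complement (0.00763, 0.416), oligodendrocyte precursor (0.00957, 0.416) and endothelial genes (0.0285, 0.499), with 0 rising. WT replicate 2 stood apart, with a mean log2 level of 3.63 for myelin genes against 5.24 and 5.27 in the other WT libraries and −0.58 for homeostatic microglia genes against 1.33 and 1.25, and 12 lists passed without it against 20 with it. Lower lists, with 0 falling, were oxidative phosphorylation (3.02e-09, 0.392), cholesterol synthesis (2.1e-07, 0.416), ribosomal protein (0.00676, 0.635), ion channel (0.0288, 0.681) and synaptic vesicle genes (0.0365, 0.663). The ion channel list turned higher without WT replicate 2 (0.389) and with a myelin term (0.608), the myelin and endothelial lists turned lower with that term, and the inhibitory neuron list turned lower in the larger batch (0.993). Chat (57.8 ± 24.1 against 56.7 ± 14.2 FPKM), Slc18a3, Isl1, Rpl22, Gfap (56.5 ± 6.29 against 92.2 ± 31.7, adjusted p = 0.835) and Aif1 (0.999) did not pass.

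In the 3-month Input Sod1 rose from 127 ± 4.88 to 7010 ± 310 FPKM (5.79 ± 0.07) and Gm8566 by 8.84 ± 0.58. Serpina3n and Serpina3m, near copies with uncertain reads, fell (−0.61 ± 0.07, 130 ± 8.78 to 85.3 ± 3.49 FPKM, and −0.94 ± 0.11), and Srd5a2, a steroid reductase, rose (2.19 ± 0.25, 0.794 ± 0.23 to 3.66 ± 0.518). The Y-linked Ddx3y (10.87 ± 0.38), Eif2s3y (9.15 ± 0.36), Kdm5d (at least 275-fold) and Uty (at least 261-fold) rose, and Xist and Tsix fell. With edgeR 7 genes rose and 4 fell of 16549, against 20 in all with DESeq2, 30 with a batch term and 3 with the 3 ages in 1 fit. Disease-associated microglia genes were higher (21, 1.35e-17, 0.083 with an estimated correlation), with 0 rising and 8 over the list alone. Also higher were homeostatic microglia (1.01e-05, 0.249), complement (0.000172, 0.147), regeneration (0.00124, 0.083), interferon (0.00624, 0.711) and proliferation genes (0.00856, 0.41), of which the interferon list turned lower without Mut replicate 2 (0.742), the library at a mean log2 level of 3.15 against 1.91 to 2.21 in the other Mut. Lists that were lower were oxidative phosphorylation (1.5e-09, 0.41), cytoskeleton (0.000487, 0.083), motor neuron subtype (0.00856, 0.147) and ribosomal protein genes (0.0107, 0.711), all with 0 members passing. The interaction of fraction and group gave 5 genes, all more positive in the IP: Atf3 (difference 3.61 ± 0.51, adjusted p = 0.0324), Phgdh (3.29 ± 0.24), Psat1 (1.09 ± 0.14), Sod1 (0.74 ± 0.11) and Ngfr. Of these 5, 1 passed in every fit without 1 library. That count was 1 without WT IP replicate 0 and 8 without WT IP replicate 1.

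At 4 months the question was which translating RNA differs at the latest age (RiboALS against RiboWT, IP, n = 3 each). Atf3 rose from 1.25 ± 0.822 to 79 ± 20.6 FPKM (6.14 ± 0.34, adjusted p = 3.34e-06) and Sprr1a from 3.86 ± 5.01 to 199 ± 112 (5.62 ± 0.61). Mustn1, a small nuclear protein of muscle and bone, rose from 0.0326 ± 0.00296 to 3.9 ± 1.04 FPKM (6.76 ± 0.44), Gdf15, a hormone released by stressed cells, from 0.0798 ± 0.0728 to 4.82 ± 1.86 (5.86 ± 0.52), and Plaur, the urokinase receptor, from 0.036 ± 0.0177 to 2.49 ± 1.33 (6.03 ± 0.58). Adm2, a peptide of the adrenomedullin family, had 0 fragments in RiboWT and rose at least 66.8-fold, and Mmp12 rose by 7.19 ± 0.70. Sod1 rose from 263 ± 21 to 20680 ± 1469 FPKM (6.31 ± 0.08) and Gm8566 by 12.60 ± 0.19. Il1f9, an interleukin of the IL-1 family (−2.06 ± 0.35, 8.84 ± 1.88 to 2.1 ± 1.19), Chst7, a sulfotransferase (−1.88 ± 0.26), Galr2, a galanin receptor (−1.42 ± 0.31), and Trbv6, a T cell receptor pseudogene (−1.89 ± 0.29), fell. With edgeR 1117 genes rose and 1169 fell of 16233, 764 of these 2286 in every fit without 1 library. Limma gave 840 (311 rising and 529 falling) and the 3 ages in 1 fit 461. The count was 864 without RiboALS replicate 0, 1011 without RiboWT replicate 0 and 1397 without RiboWT replicate 1. RiboWT replicate 0 was the only library without Y-linked transcripts (Ddx3y), and 1033 genes passed with a term for these.

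By list, 24 of 46 oxidative phosphorylation genes fell at 4 months and 0 rose (36 over the list alone), with a camera adjusted p of 2.69e-15, or 0.49 with an estimated correlation. Ndufb8, a subunit of complex I, fell from 3346 ± 271 to 2366 ± 191 FPKM (−0.46 ± 0.07), and Atp5j, of ATP synthase, from 1224 ± 87.8 to 912 ± 87.8 (−0.44 ± 0.07). Of 23 cholesterol synthesis genes 16 fell (9.16e-12, 0.49), among them Mvk, mevalonate kinase, from 93.7 ± 6.47 to 51.3 ± 8.84 FPKM (−0.80 ± 0.09), Hsd17b7 (−0.81 ± 0.06) and Fdps (−0.65 ± 0.07). Of 69 ribosomal protein genes, many with processed copies, 9 fell (8.56e-09, 0.495), and Rpl22l1, the paralog of the tagged protein's gene, went from 200 ± 10.5 to 130 ± 8.45 FPKM (−0.61 ± 0.08). Rpl22 itself fell from 30.6 ± 4.82 to 20.8 ± 2.54 FPKM (−0.33 ± 0.09). Of 36 ion channel and receptor genes 12 fell and 1 rose (0.00683, 0.503), with Kcna1, a potassium channel, at −0.43 ± 0.07. Of 27 cytoskeleton genes 6 fell and 1 rose (0.0478, 0.693), and the neurofilament genes Nefl (5961 ± 278 to 4283 ± 424 FPKM, −0.47 ± 0.07), Nefm (−0.41 ± 0.07) and Nefh (−0.39 ± 0.08) fell. Among 5 blood genes Hba-a2 fell (−1.03 ± 0.29; 0.0129, 0.495), a hemoglobin gene with a near copy and so uncertain.

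Of 36 regeneration genes 22 rose and 1 fell (1.38e-10, 0.49 with an estimated correlation), with Sox11, a growth transcription factor, up by 1.11 ± 0.14. Of 29 stress response genes 14 rose and 0 fell (9.31e-09, 0.49): Ddit3, the factor CHOP, from 38 ± 2.27 to 147 ± 43.4 FPKM (1.91 ± 0.18), Slc7a5, an amino acid transporter, from 15.8 ± 4.46 to 39.5 ± 10.1 (1.33 ± 0.12), Phgdh from 1.38 ± 0.642 to 12.2 ± 5.18 (3.00 ± 0.35) and Nupr1, a stress-induced nuclear protein, by 3.32 ± 0.33. Of 19 interferon genes 14 rose (2.38e-09, 0.495), with Rsad2, which blocks viral replication, from 0.565 ± 0.404 to 5.82 ± 4.21 FPKM (3.81 ± 0.66) and Ifi44 by 4.99 ± 0.88. Disease-associated microglia genes rose in 10 of 16 cases and fell in 1 (7.69e-06, 0.49), with Cd68, of phagocyte lysosomes, from 0.656 ± 0.281 to 7.46 ± 3.04 FPKM (3.92 ± 0.32) and Gpnmb by 2.69 ± 0.25. Homeostatic microglia genes rose in 5 of 11 cases (0.000722, 0.49), complement genes in 5 of 7 (0.000835, 0.49), with C1qa from 3.1 ± 0.768 to 16 ± 11.2 FPKM, and Gfap (37.8 ± 12.8 to 146 ± 110, 1.99 ± 0.43) and Aif1 (1.58 ± 0.44) rose. Myelin genes did not pass (15, adjusted p = 0.492, 0 rose and 0 fell), nor did astrocyte genes (4 rose, 1 fell, 0.416).

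The motor neuron list was split at 4 months (adjusted p = 0.911, 4 of 14 rose and 5 fell). Ret and Gfra1, receptors for GDNF family factors, rose by 0.68 and 0.42 log2, with Chrna4 and Slc5a7, and Isl2, Lhx4, Nefh, Prph and Slc10a4 fell. Among 15 subtype genes 2 rose, Wnt7a and Sv2a, and 4 fell, with the fast motor neuron genes Mmp9 and Chodl at −0.70 and −0.94 (adjusted p of the list 0.911). Lysosome genes rose in 11 of 30 cases and fell in 2 (0.0572), neuropeptide genes rose in 5 and fell in 3 of 17 (0.51), synaptic vesicle genes rose in 5 and fell in 2 of 22 (0.911), p53 targets rose in 5 and fell in 2 of 23 (0.148), immediate early genes rose in 4 of 14 (0.0512) and heat shock genes in 0 of 19 (0.0572). Chat (76.3 ± 4.58 against 84.7 ± 4.17 FPKM, adjusted p = 0.139), Slc18a3 (0.669) and Isl1 (0.987) did not pass.

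In the 4-month Input (n = 3 each) Sod1 rose from 99.2 ± 16.1 to 5419 ± 362 FPKM (5.78 ± 0.12) and Gm8566 by 12.49 ± 0.18. Sprr1a (0.314 ± 0.154 to 13.1 ± 4.94 FPKM, 5.41 ± 0.39), Atf3 (0.55 ± 0.169 to 10.5 ± 5.6, 4.06 ± 0.38), Fgf21 (4.27 ± 0.49) and Mmp12 (5.54 ± 0.58) rose, and Meg3, a long noncoding RNA of neurons, fell from 173 ± 6.53 to 130 ± 8.35 FPKM (−0.45 ± 0.05). With edgeR 6 genes rose and 1 fell of 17923, against 2909 at an unadjusted p under 0.05, 857 with DESeq2, 19 with limma, 944 with no filter and 748 with the 3 ages in 1 fit. Without RiboALS replicate 1, 1172 genes passed, without RiboALS replicate 2, 170, and without RiboWT replicate 0, 3. Gfap (663 ± 29.6 against 2117 ± 1020 FPKM, 1.70 ± 0.30, adjusted p = 0.0957), Cd68 (11 ± 0.818 against 69.2 ± 44.4, 0.0957), Aif1 (0.0962), Chat (10.2 ± 0.158 against 7.94 ± 0.94, 0.115), Slc18a3 (0.173), Isl1 (0.511) and Rpl22 did not pass.

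Of Input lists at 4 months 22 passed at the preset correlation, with adjusted p-values of 0.306 to 0.437 when the correlation was estimated. Higher lists over the list alone had 19 of 22 disease-associated microglia genes rising (4.85e-18, median 2.45), 20 of 20 interferon genes (7.6e-16, 2.33), 12 of 12 homeostatic microglia genes (2.42e-11), 10 of 12 complement genes (2.06e-09), 11 of 12 antigen presentation genes (5.61e-08), 19 of 37 regeneration genes (1.04e-07), 8 of 21 proliferation genes (2.66e-07), 8 of 16 astrocyte genes (8.71e-05), 6 of 18 matrix genes (0.000896), 13 of 30 lysosome genes (0.00131), 3 of 16 immediate early genes (0.00337) and 1 of 10 oligodendrocyte precursor genes (0.0176). Lower lists were oxidative phosphorylation (9.82e-11), ion channels (1.18e-09), cholesterol synthesis (1.3e-08), synaptic vesicle (5.71e-07), cytoskeleton (2.81e-06), motor neuron (6.45e-06), motor neuron subtype (0.00289), mitochondrial genome (0.00603), blood (0.00992) and inhibitory neuron genes (0.0126). Of 14 motor neuron genes 9 fell and 1 rose over the list alone and 0 over all genes, with Mnx1 at −0.64 ± 0.14 (adjusted p = 0.0965). Chodl, of the subtype list, was at −1.21 ± 0.16 (0.0772).

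The interaction of fraction and genotype at 4 months gave 89 genes more positive and 36 less positive in the IP, 14 of 125 in every fit without 1 library, and 18 in all without RiboWT Input replicate 0. Mustn1 (6.16 ± 0.63, adjusted p = 0.00253), Aqp9, a glycerol channel (5.17 ± 0.76), Phgdh (3.02 ± 0.40), Slc13a5, a citrate carrier (2.95 ± 0.52), and Cdk15 (2.76 ± 0.58) were more positive in the IP. Cdk1, the mitotic kinase (−2.22 ± 0.47), Tgfb1, a cytokine (−1.96 ± 0.34), Chst7 (−1.94 ± 0.31) and Lxn (−1.56 ± 0.32) were less positive. Chat differed by 0.54 ± 0.11 and did not pass (adjusted p = 0.051).

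Change with age was tested as differences of the RiboALS effect in the IP (n = 3 per group, with 4 Mut libraries at 3 months). From 1 to 3 months Atf3 (5.48 ± 0.67, adjusted p = 0.0181) and Fgf21 (3.63 ± 0.39) became more positive, 2 genes by edgeR against 875 at an unadjusted p under 0.05, and 0 without 3-month WT replicate 1. From 3 to 4 months 0 genes passed with edgeR, with 529 at an unadjusted p under 0.05 and 4 without 4-month RiboWT replicate 0. In simulated data that test recovered 27% of 2-fold and 84% of 4-fold changes, so smaller changes could be missed. Both differences use 3-month groups in which Y-linked genes such as Ddx3y follow the tables' names. Between 1 and 4 months 116 genes became more positive and 147 less, 20 of 263 in every fit without 1 library. The count was 24 without 1-month RiboALS replicate 0 and 1685 without 1-month RiboWT replicate 0. They include Mmp12 (9.40 ± 2.05), Aqp9 (7.68 ± 1.42), Plaur (7.47 ± 1.31) and Atf3 (6.14 ± 0.77) upward, and Adam33, a metalloprotease (−2.32 ± 0.34) and Scgn, a calcium binder (−1.45 ± 0.26), downward. Part of the difference for Aqp9 and Plaur came from 1-month effects of −2.08 and −1.44, which did not pass, while that of Atf3 was −0.01. Glial transcript levels differed widely between the 1-month IP libraries. Of genes that rose at 3 months, 7 of 11 rose at 4 months: Atf3, Fgf21, Mmp12, Phgdh and Psat1, with Sod1 and Gm8566, which genotype sets. The other 4 of the 11 are Y-linked.

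The last question was how the RiboALS response compares with the injury response in the IP (n = 3 per group). Per the labels, the injury samples hold only some lumbar segments and the ALS samples the entire lumbar cord. Of 236 genes up at D7 and 1080 up in 4-month RiboALS, 111 rose in both, against 16.3 by chance (of 15632 genes, one-sided Fisher exact p = 7.93e-66). They include Ccl7 (8.71 at D7 and 3.88 in RiboALS), Gpr151 (7.80 and 3.53), Atf3 (7.07 and 6.14), Cd63 (2.22 and 1.33), Gal (5.61 and 1.01), Timp1 (5.52 and 4.10), Gap43 (2.54 and 1.13) and Cd44, a hyaluronan receptor (2.62 and 2.01). Htr3a and Tcea3 fell in both (2 genes, 0.523 by chance, one-sided Fisher exact p = 0.0911), and Serpina3m (1.27 and −0.71) and Fabp5 (0.97 and −0.33) rose at D7 and fell in RiboALS. The Fisher tests treat genes as independent, which they are not, so these p-values do not measure spread between mice. At 3 months Atf3 was the 1 gene shared with D7, and at 1 month there was 0. Over all 15632 genes tested in both, the log2 changes at D7 and 4 months correlated at r = 0.327 (rho = 0.154) with 54.6% of the same sign, and over 243 genes chosen for passing at D7 at r = 0.653 (rho = 0.528).

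**Figure D3:**
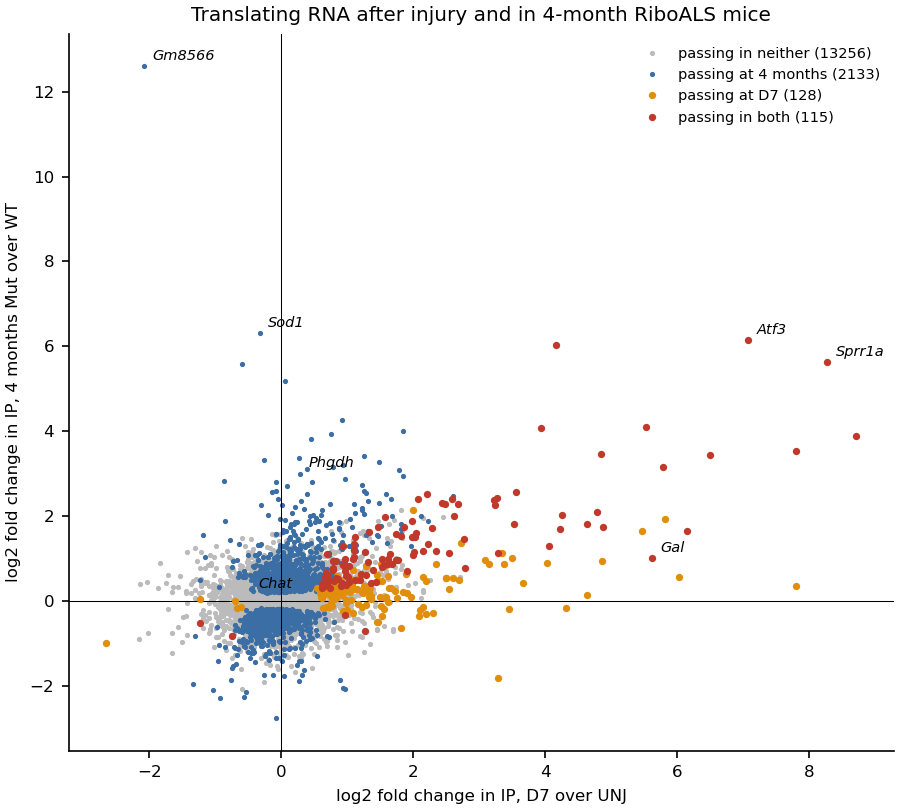
Log2 fold change in the IP after injury and in 4-month RiboALS, with genes passing in either or both.

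An interaction test gave 32 genes with a more positive change in 4-month RiboALS than at D7 and 105 with a less positive one, 52 of 137 in every fit without 1 library. The count was 61 without UNJ replicate 1 and 939 without UNJ replicate 0. Apart from Sod1 (6.61 ± 0.17), Gdf15 (6.41 ± 0.83, adjusted p = 0.00104), Aqp9 (6.17 ± 1.15), Mustn1 (5.99 ± 1.11) and Fgf21 (5.12 ± 0.64) were more positive in RiboALS. Fst (−7.50 ± 0.77, adjusted p = 9.24e-05), Ctla2a, a protease inhibitor (−5.48 ± 0.46), Grp (−5.14 ± 0.71), Ankrd1, a stress-induced nuclear protein (−4.94 ± 0.92), and Gal (−4.62 ± 0.47) were less positive. The Atf3 changes were not told apart (−0.95 ± 0.63, adjusted p = 0.58).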

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

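Of the tests in this part, the interaction tests and the glial carry-over test of interferon genes were written before the results were seen, and the other tests of explanations, including those on regrouped libraries, were chosen after.

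Groups of 4 libraries, at 3 months, were searched for single libraries far from the rest (Dixon test on each named gene, which by chance flags about 1 in 20 groups), and 17 of 146 genes stood out. In the IP, the library named Mut replicate 2 was high for myelin genes, Cnp at 120.4 FPKM against 77.34, 77.48 and 72.49, and Trf at 291.2 against 119.8, 124.5 and 139.5, and for Olig2 of the same lineage at 5.364. It was high for complement genes of microglia, C1qa at 49.08 against 6.069, 6.259 and 6.418, C1qb at 64.85 and C1qc at 41.77, and for the microglial genes Cx3cr1 at 8.115 and Tmem119 at 13.95. The same library stood apart for H2-K1, which presents antigen (20.21), Gad2 and Slc32a1 of inhibitory neurons (8.143 and 5.19), Scg2 of secretory granules (179.2) and Rab3a of synaptic vesicles (1631). Lcn2, a lipocalin of reactive astrocytes, was low in IP Mut replicate 3 at 28.97 against 36.92, 37.44 and 37.82. In the Input, Gfap was low in Mut replicate 0 at 828.6 against 1147, 1086 and 1117, Wnt7a was apart in the same library at 18.47, and Psmb8 was apart in Mut replicate 3 at 6.441. IP Mut replicate 2 and Input Mut replicate 0 belong to the smaller 3-month batch, which was inferred from Rn18s-rs5 shares. The other IP library of that batch, WT replicate 2, was the lowest for myelin and homeostatic microglia genes (mean log2 3.63 and −0.58).

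Genes stood out where an effect differed between fractions, ages or conditions by an edgeR interaction test. For injury, IP minus Input, these were Npy 5.547, Crym 5.144, Gpr151 4.996, Cyp26a1 4.468, Gal 4.226 and Itgb5 −0.6598. For 3 months they were Atf3 3.612, Phgdh 3.289, Psat1 1.086 and Sod1 0.7439. For 4 months they were Mustn1 6.161, Aqp9 5.169, Phgdh 3.021, Slc13a5 2.949, Cdk15 2.765, Mfsd7c −3.785 (IP levels of 0.0516 and 0.0028 FPKM, near 0), Cdk1 −2.222, Tgfb1 −1.964, Chst7 −1.941 and Lxn −1.561. Between 1 and 3 months the IP effect moved for Atf3 by 5.476 and Fgf21 by 3.626. Between 1 and 4 months it moved for Mmp12 by 9.404, Aqp9 7.676, Plaur 7.473, RP23-477L20.1 7.233, Cd68 6.93 (−2.998 at 1 month, where glial levels were uneven between libraries, and 3.922 at 4 months), Atf3 6.143, Adam33 −2.317, Ppp1r1c −2, Trbv6 −1.887, Lxn −1.618 and Scgn −1.447. Between injury and 4-month RiboALS it moved for Sod1 by 6.609, Gdf15 6.406, Aqp9 6.166, Mustn1 5.989, Fgf21 5.122, Fst −7.498, Ctla2a −5.479, Grp −5.141, Ankrd1 −4.937 and Gal −4.618.

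Glial lists were lower in the 1-month RiboALS IP. Uneven carry-over of RNA from other cells could give this, since the mean log2 level of the myelin list ranged over 3.105 between the 3 RiboWT IP libraries, more than the group difference of −1.284. A loss of glial transcripts from the cord was excluded by the Input, where the median log2 change of the same genes was −0.02641 against −1.218 in the IP. Which RiboALS genes are changed in motor neurons beneath this carry-over stays open.

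Interferon genes rose in the 4-month RiboALS IP. Glial carry-over at the usual share was excluded: their rise in the IP was 0.2447 of their rise in the Input at the median (quartiles 0.124 and 0.331), above the highest glial share of IP over Input of 0.09172. Myelin and precursor genes changed by a median of 0.09347 against 1.569 for interferon genes. This excludes a larger share of oligodendrocyte RNA, though not of microglial RNA. Compared in the same way, homeostatic microglia genes were higher by 0.0572 of their Input rise, disease-associated microglia genes by 0.0635 (quartiles 0.0516 and 0.323) and astrocyte genes by 0.0748, near the glial share, over the 8, 13 and 7 members over 1.5 times higher in the RiboALS Input, so the rise of the microglia lists, with Cd68, C1qa and Gfap, could be carry-over from a changed cord. Some disease-associated microglia genes reached the ratio of interferon genes, so carry-over of interferon transcripts from changed microglia stays open, and cells outside these lists were not tested.

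Few genes passed in the 4-month Input. A RiboALS library with a smaller response could explain this, since 1172 genes passed without RiboALS replicate 1, against at most 170 without any other library and 7 with all. A swap or large mixture with a RiboWT sample was excluded by its Sod1 level, 1.08 times the mean of the other RiboALS Input libraries. Sod1 cannot exclude a small mixture or a wrong age label. RiboALS Input libraries stood at 5827.1 to 6251.7 FPKM at 1 month and 5010.5 to 5699.5 at 4 months. Whether the mouse of RiboALS replicate 1 was younger or at an earlier stage stays open.

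To ask what chance regrouping gives, each test was repeated on other splits of the same libraries. For 3 against 3 libraries there are 10 splits, too few to exclude chance. There the real count of IP genes and the highest other were 296 and 2 for D7 (1 split as large), 2 and 1153 for 1 month (2 as large) and 2286 and 3 for 4 months (1). For Input genes they were 187 and 5 (1), 3 and 14 (2), and 7 and 2 (1). For IP lists they were 15 and 11 (1), 19 and 21 (2), and 12 and 23 (3), and for Input lists 12 and 16 (3), 7 and 13 (8), and 22 and 22 (2). The split with 1153 genes at 1 month set the 3 IP libraries with the highest myelin levels (7.66, 6.86 and 6.48) against the other 3 (4.355 to 4.555), so it follows the myelin level. At 3 months there were 35 splits. The IP count of 13 genes was above the highest other of 1 (1 as large), but 4 of the 13 are Y-linked, 2 are Xist and Tsix and 2 are Sod1 and its copy, which sex and genotype fix. The other 5 still exceed 1, so chance was excluded for the count only over splits that mix the library batches. Splits within the batches were not run, so chance stays open there (112 genes passed with a batch term, the 13 among them). Sex could not be told from group at 3 months. Chance was not excluded for IP lists (20 against 20, 2), Input genes (11 against 1140, 2) or Input lists (10 against 14, 6).

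Interactions were set against 30 drawn splits, with each of the 2 joined tables regrouped on its own. A draw can thus keep or mirror the real groups of 1 table and hold that table's own effect. High counts therefore cannot decide chance for an interaction. For IP minus Input at 3 months 5 genes stood against at most 4 (1 as large), and 1 of the 5 is Sod1, set by genotype, so chance stays open for the rest. Chance was likewise left undecided for IP minus Input at D7 (83 against 158, 2) and 4 months (125 against 1661, 4), 3 minus 1 months (2 against 164, 2), 4 minus 1 months (263 against 403, 4) and 4-month RiboALS minus D7 (137 against 1134, 3). For IP minus Input at 1 month (0 against 1356, 30) and 4 minus 3 months (0 against 0, 30) no gene passed in the real split, so every split is as large and these counts test nothing.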

How the results depend on the processing

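Of the settings in this part, the library batch, larger batch, myelin level and Y-linked terms were chosen after results were seen. Limits: 3 libraries per group, no mouse ID in the tables, groups at 3 months that differ in sex and are named differently in labels and tables, and sex not given in the labels. The planned covariate from sample number ranges and the mouse block for interactions were not run. Where a setting moved a value, the cause was not tested.

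Settings that moved counts of genes over 1.5 times, by comparison, were as follows. IP at D7 (296): limma 146 and 136 (1 and 0.1 added), no filter 496. IP at 1 month (2): DESeq2 5, limma 4 and 6, 3 ages in 1 fit 4. IP at 3 months (13): DESeq2 103, batch term 112, larger batch 172, myelin term 8. IP at 4 months (2286): limma 840 and 817, 3 ages in 1 fit 461, Y-linked term 1033. Input at D7 (187): limma 39 and 39, no filter 362, replicate block 327. Input at 1 month (3): DESeq2 12, limma 8 and 6, no filter 123. Input at 3 months (11): DESeq2 20, 3 ages in 1 fit 3, batch term 30, larger batch 19. Input at 4 months (7): DESeq2 857, limma 19 and 19, no filter 944, 3 ages in 1 fit 748, Y-linked term 3.

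Lists passing with an estimated correlation were 1, 0, 0 and 0 in the IP and 2, 0, 0 and 0 in the Input (D7, 1, 3 and 4 months). With fry they were 2, 0, 2 and 3, and 3, 1, 2 and 0. With a myelin term 9 passed in the 1-month IP and 11 in the 3-month IP.

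Without 1 library, gene counts lay at 189–313, 2–2, 9–16 and 864–2663 in the IP and 86–1.8e+02, 2–6, 8–9 and 3–1172 in the Input. Interaction counts lay at 55–160, 0–1, 1–8 and 18–1.8e+02 (IP minus Input), 0–2, 0–4 and 24–1685 (between ages) and 61–939 (4-month RiboALS minus D7). List counts lay at 12–19, 13–20, 12–25 and 12–18 in the IP and 11–15, 5–10, 4–14 and 19–28 in the Input.

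List directions that turned round, with the camera adjusted p in that setting (and its range over all fits without 1 library), were these. Without 1 library: oxidative phosphorylation at D7 IP 0.00469 (UNJ 0, 0.00469–0.62), 1 month IP 0.00277 (RiboWT 0, 1.84e-06–0.593) and 1 month Input 1.25e-05 (RiboWT 1, 4.99e-08–0.995), ribosomal protein at 1 month IP 0.762 (RiboWT 0, 2.37e-07–0.762), D7 Input 0.485 (UNJ 0, 3.74e-08–0.485) and 4 months Input 0.00118 (RiboWT 1, 0.00118–0.545), ion channels at 3 months IP 0.389 (WT 2, 4.28e-05–0.389) and interferon at 3 months Input 0.742 (Mut 2, 7.0e-05–0.742). With a myelin term at 1 month IP: astrocyte 0.181, myelin 0.669, endothelial 0.00696, excitatory interneuron 0.564 and matrix 0.0162, and at 3 months IP: ion channels 0.608, myelin 0.938 and endothelial 0.796. In the larger batch at 3 months IP: inhibitory neuron 0.993.

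The shared D7 and 4-month falls were 9 at an adjusted p under 0.1 and 19 by the authors' calls. By those calls D7 shared 18 rises with 3 months and 2 with 1 month, and 3 and 4 months shared 35 rises and 1 fall. The 3-month control median of motor neuron IP over Input became 2.44. No gene passed in opposite directions in any setting, and 125 named genes changed sign without passing in either.

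The replicate number as a block at D7 gave 295 IP genes (270 shared) and 327 Input genes (187 shared), and 17 and 13 lists. Deviations of same-numbered D7 and UNJ libraries correlated at 0.044, 0.112 and 0.032 in the IP and 0.098, 0.069 and 0.166 in the Input. Other pairs lay between −0.105 and 0.059 in the IP and between −0.105 and 0.011 in the Input. Whether the numbers pair the libraries stays open. Each D7 Input library correlated best with the UNJ library of its own number, as 2 of 3 did in the IP, where D7 replicate 2 was nearer UNJ 0 (0.059).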

Other observations

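All comparisons in this part were chosen after the results were seen, except the interaction and overlap tests named as such.

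The ratio of IP to Input FPKM at 4 months was, for Chat, 10.7 in RiboALS and 7.44 in RiboWT, for Slc18a3 16.1 and 12.7, for Isl1 9.53 and 7.17, and for Prph, a filament of peripheral axons, 18.4 and 16.2. At 1 month Chat stood at 7.45 and 7.91 and Slc18a3 at 13.8 and 15.2. Over the 14 motor neuron and cholinergic genes the median log2 ratio was 3.06 in RiboALS and 2.87 in RiboWT at 4 months, and 2.98 and 2.83 at 1 month. These ratios were not tested as a list, and for Chat the edgeR interaction did not pass (adjusted p = 0.051). Gfra1 of the GDNF receptor rose after injury (0.92 ± 0.18, n = 3 each) and in 4-month RiboALS (0.42), and Ret, its partner, rose in RiboALS from 64 ± 4.64 to 103 ± 5.63 FPKM in the IP and stood at 22.2 ± 1.18 and 24.1 ± 1.26 in the Input.

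Over 2261 genes chosen for passing at 4 months, the 3-month log2 changes had the same sign in 90.5% and correlated at r = 0.866 (rho = 0.828). Over all 15840 genes tested in both it was r = 0.531, with 67.8% of the same sign. By edgeR 13 genes passed at 3 months, and 7 of the 11 that rose also rose at 4 months. Libraries with Y-linked transcripts were unevenly split between the groups at both ages, and how far sex adds to this likeness was not tested. Against 1 month the genes passing at 4 months correlated at r = −0.109. The authors' own Cuffdiff calls (q under 0.05) were 294 higher and 48 lower in the D7 IP, 7 and 196 at 1 month, 50 and 3 at 3 months, and 703 and 669 at 4 months, of which edgeR shared 209 and 7, 2 and 0, 7 and 0, and 583 and 608, with 0 in opposite directions. In the Input the authors' calls were 147 and 8, 0 and 0, 14 and 8, and 613 and 64. Of these edgeR shared 118 and 3, 0 and 0, 5 and 2, and 5 and 0.

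Sex was read from Ddx3y, which was over 1 FPKM in 0 of 3 D7 and 0 of 3 UNJ IP libraries, in 2 of 3 RiboWT and 2 of 3 RiboALS at 1 month, in 0 of 3 WT and 4 of 4 Mut at 3 months, and in 2 of 3 RiboWT and 3 of 3 RiboALS at 4 months. Where present in the IP it lay between 14.9 and 20.8 FPKM.

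The hypothesis drawn from the 3-month data is that serine synthesis is induced within motor neurons of RiboALS mice by 3 months. Phgdh and Psat1 rose in the IP by 3.16 ± 0.25 and 0.99 ± 0.11 and more than in the Input by 3.29 ± 0.24 and 1.09 ± 0.14 (edgeR interaction, adjusted p = 2.57e-05 and 0.0139), but 1 of the 5 genes of that interaction passed in every fit without 1 library, and the count lay between 1 and 8 over those fits. Since all Mut and no WT libraries held Y-linked transcripts, sex could contribute at 3 months. At 4 months 2 of 3 RiboWT and 3 of 3 RiboALS IP libraries held these transcripts. There Phgdh and Psat1 rose too, by 3.00 and 1.28, which argues against sex alone for these 2 genes. PHGDH staining in identified motor neurons of male and female littermates at 3 months would test the hypothesis, which predicts more PHGDH in RiboALS of either sex.

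Another hypothesis is that motor neurons themselves mount part of the interferon response at 4 months. The IP rise was 0.2447 of the Input rise for interferon genes against 0.09172 for the highest glial share, and for Rsad2 it was 1.4. The quartiles of the interferon genes, 0.124 and 0.331, overlap those of disease-associated microglia genes, 0.0516 and 0.323, so a microglial source stays open. In situ hybridization of Rsad2 and Bst2 with Chat would tell neuronal from glial transcripts, and a neuronal source predicts signal within Chat-positive cells.

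A further hypothesis is that some genes of the injury programme respond less in RiboALS motor neurons. Of D7 rises 111 were shared (16.3 by chance), while the RiboALS effects of Fst, Grp and Gal were less positive than those at D7 (by −7.50 ± 0.77, −5.14 ± 0.71 and −4.62 ± 0.47, edgeR interaction). Regrouped libraries gave up to 1134 such genes against 137. Such draws can hold the effect of 1 comparison alone, so chance was not decided for that count. Nerve injury in RiboALS and RiboWT littermates at 4 months would test it: a blunted programme predicts a smaller rise of Gal and Fst in injured RiboALS motor neurons.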
